A study of Mus musculus with 9 samples.

How the data were processed

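Affymetrix expression arrays of mouse distal small intestine were analysed from 45101 probe sets on 9 arrays. Per the labels' protocols, biotin-labelled cRNA was made from 20 µg of total RNA. The deposited values were linear intensities, with a lowest value of 1 and a highest of 21694. What software the authors used to compute these intensities, and whether they scaled the arrays, is not given in the sources used here. Columns were matched to samples by name, and groups and replicate numbers were taken from the sample titles. No column was left unmatched. Rag1, BP and wild type had 3 arrays each, and the labels give no sex, batch or date.

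Array medians started at 29.4 and trimmed means ran from 100.3 to 141, a difference of more than 10%, so by a rule made before the data were examined the arrays were quantile-normalized after log2(value + 16). The 64 control probe sets were left out of the tests but kept as measures of array quality. Probe sets in the lowest 40% by mean over all 9 arrays were left out too (a mean of 5.30 on the log2 scale, about 23.5 in intensity), which kept 27022. Fold changes are on the log2(value + 16) scale and understate the change of dim genes. The files give no detection calls, so no probe set was declared absent.

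Gene symbols came from the platform annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 had none. The gene identifiers of 34741 single-symbol probe sets were found in a RefSeq gene table of assembly GRCm38.p6 and those of 204 were not, and 0 symbols needed updating. The files name no genome build, so no coordinates are given. No gene was named from a probe set with several symbols. A gene was represented by its tested probe set with the highest mean, which gave 13570 genes.

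Differences were tested with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8): 1 mean per group, all 9 arrays in 1 fit with a shared spread (6 residual degrees of freedom), empirical Bayes moderation with an intensity trend, two-sided, and Benjamini-Hochberg adjustment over all 27022 probe sets, with a threshold of 0.05. The contrasts were BP minus Rag1, wild type minus Rag1 and wild type minus BP. A fixed set of 26 gene lists was tested with camera at its preset correlation of 0.01 against all other genes, with Benjamini-Hochberg adjustment over the 25 lists of a comparison that had at least 5 tested genes. The sex-linked list had 3 tested genes and was described only. Camera with an estimated correlation and fry were alternatives. The lists covered immune and other cell types, antigen presentation, interferon, antimicrobial, stress, cytokine, lipid, cholesterol, bile acid, xenobiotic, digestion, cell cycle, crypt, unfolded protein, clock and immediate early genes, and genes near Rag1.

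The genes named were chosen by a rule fixed at the same point. They were, for each comparison and direction, the 12 largest changes past the threshold whose 3 arrays of one group all lay beyond the 3 of the other, with at most 3 immunoglobulin or T cell receptor genes, clone and predicted genes left out; up to 4 called members per list, or up to 2 with the smallest p where none passed; and Rag1, Igha, Jchain, Cd3e, Pigr, Nos2, Reg3g and the sex-linked genes. Not every gene the rule allows is printed. The dimmer probe set of Pigr was given because it differed from the brighter one. The control probe sets and the genes shared between comparisons were singled out after their values were seen.

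The fit and the list test were tested on simulated data, with 200 changed probe sets in each of 5 datasets. Each probe set had its real mean and moderated variance, the same on all arrays, and probe sets were drawn independently. The rates below therefore do not cover the larger spread of the BP arrays or correlation between the genes of a list. For BP against Rag1, 90.8% of changes of 2 on the log2 scale, 16.7% of changes of 1 and 0% of changes of 0.5 were recovered among 27022 probe sets, with 6.70% false calls. For wild type against Rag1 these were 88.3%, 11.4%, 0.92% and 5.81%. A list shifted by 0.5 was called in 5 of 5 datasets, and 0 of 120 tests of other lists were.

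The alternatives tried were centring on the median, the pseudocounts 1 and 64, no filter, leaving out the lowest 60%, fitting only the groups compared, a replicate block, no intensity trend, robust moderation, array weights, a fold of at least 1.5, a threshold of 0.01, all probe sets of a gene, and leaving out each array. Quantile normalization had been listed as an alternative and became the main setting. Alternatives chosen after seeing the data were the values as deposited, the actin ratio as a covariate, leaving out arrays with a high actin ratio or a high Xist signal, and a filter by group. The covariance of unchanged groups was also simulated, after seeing the data, for the pseudocount 64 and without wild type replicates 1 and 3. Figures were drawn from the same values.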

Results

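The arrays measured messenger RNA in the distal small intestine of mice that had been colonized for 10 days with Bacteroides thetaiotaomicron, a bacterium of the normal gut flora. The gut had been divided into 16 equal pieces, and pieces 10, 11, 12 and 14 were pooled for each RNA sample, so the samples hold epithelium, immune cells, muscle and nerve together. There were 9 arrays in 3 groups of 3. The Rag1 group came from mice named for Rag1, a gene needed to assemble antibody and T cell receptor genes. The BP group was labelled as Rag1 tissue with the added name BP, which the labels do not spell out. The wild type group came from B6 mice. The series title asks what IgA, the antibody class secreted into the gut, does to this tissue after colonization. The labels do not say whether each array stands for a separate mouse, so the p-values measure the spread between these samples only, and 3 arrays per group limit the precision.

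In all, 27022 of 45037 non-control probe sets were bright enough to be tested. After normalization the median standard deviation of a probe set within a group was 0.21 on the log2 scale for Rag1, 0.44 for BP and 0.23 for wild type. Some of the BP arrays stood apart in their control signals. The ratio of 3' to 5' signal of the beta-actin control, which grows when RNA is shortened, was 1.53 to 1.77 on the Rag1 arrays and 3.25, 1.76 and 4.17 on wild type replicates 1, 2 and 3. It was 14.2, 2.43 and 20.2 on BP replicates 1, 2 and 3. BP replicate 2 alone had a strong signal for the Dap control, 1019 against at most 19.1 on any other array. Several sex-linked probe sets also split the arrays, and others did not. The brightest probe set of Xist, expressed from the inactive X chromosome of females, read 5.84 to 24.1 on the Rag1 arrays, 36.0, 624 and 1735 on BP replicates 1, 2 and 3, and 1086 to 1539 on the wild type arrays. Another Xist probe set did not follow this pattern. It read 33.0 to 47.8 on the Rag1 arrays, 26.4 to 69.6 on the BP arrays and 26.5 to 32.8 on the wild type arrays. Eif2s3y, a Y-linked gene, read 44.9 to 109 on the Rag1 arrays, 17.0 on BP replicate 1 and at most 7.22 on every other array. Kdm5d, also Y-linked, read 65.7 to 84.0 on the Rag1 arrays, 43.1 on BP replicate 1 and at most 12.7 elsewhere, though its change from Rag1 to wild type did not pass (-1.88 ± 0.40, adjusted p = 0.119). The other Eif2s3y and Kdm5d probe sets, too dim for the tests, did not separate Rag1 from wild type. The tested probe set of Uty, Y-linked as well, went another way: it was highest on BP replicate 2, at 112. It did not separate wild type from Rag1 (-0.61 ± 0.39, adjusted p = 0.999). Among dimmer, untested Uty probe sets, 1 read 15.6 to 36.9 on the Rag1 arrays and at most 8.96 elsewhere. The remaining ones did not set the Rag1 arrays apart from all others. Sex and group therefore could not be told apart between wild type and Rag1. In the brightest Xist, Eif2s3y and Kdm5d probe sets, BP replicates 2 and 3 lay nearer to the wild type arrays. BP replicate 1 lay near the Rag1 arrays for Xist and between Rag1 and wild type for Eif2s3y and Kdm5d. Sex was therefore partly tied to group between BP and Rag1 too.

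**Figure D1:**
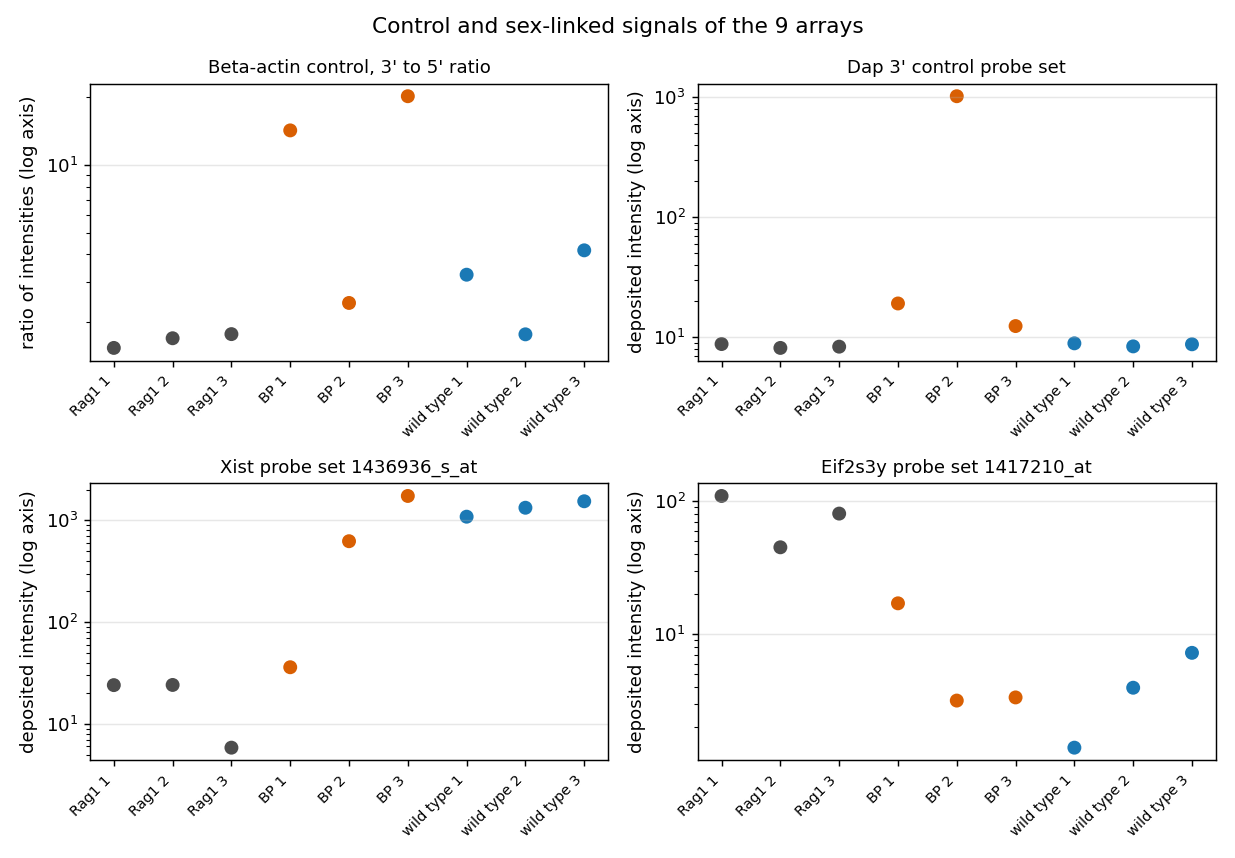
Each point is 1 of the 9 arrays, ordered by group and replicate, with the vertical axes logarithmic. The panels show the beta-actin 3' to 5' intensity ratio and the deposited intensities of the Dap control, Xist and Eif2s3y; BP replicates 1 and 3 have the highest actin ratios (14.2 and 20.2), and BP replicate 2 has the highest Dap signal (1019).

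The gene named by the label was too dim to check it. The Rag1 probe set read 1.37 to 2.69 on the Rag1 arrays, 2.87 to 22.8 on the BP arrays and 3.54 to 17.6 on the wild type arrays, all below the brightness needed for testing, and its place relative to the deleted part of the gene is not given in the sources used here. Genes that need Rag1 activity separated wild type from the other groups, while Rag1 and BP overlapped. Igha, the constant region of the IgA heavy chain, read 83.4 to 93.4 on the Rag1 arrays, 54.5 to 111 on the BP arrays and 2583 to 6389 on the wild type arrays. Cd3e, a chain of the T cell receptor complex, read 21.3 to 27.3, 16.2 to 44.6 and 112 to 154 in the same order.

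The comparison of wild type with Rag1 tissue asked how the gut transcriptome differs when adaptive lymphocytes are present. Transcripts of antibody-producing cells, T cells and cytotoxic cells were higher on the wild type arrays, together with antigen presentation and interferon response genes. A smaller set of genes, epithelial defence genes among them, was lower at the threshold used. Igha was higher by 5.44 ± 0.37 on the log2 scale (SE, n = 3 per group; adjusted p = 3.61e-05), and Jchain, which links IgA units, by 5.80 ± 0.48 (adjusted p = 0.00016). Reg3g and Reg3b, which encode antibacterial lectins of the intestinal epithelium, fell by 2.37 ± 0.30 (adjusted p = 0.00431) and 1.93 ± 0.22 (adjusted p = 0.00212). In all, 70 probe sets were higher and 19 lower on the wild type arrays at an adjusted p under 0.05 in limma, which stood for 47 and 12 genes.

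Among B cell and plasma cell genes, 3 of 22 tested members rose, namely Igha, Jchain and Iglv1, and 8 rose when p was adjusted over the list alone. The kappa segment Igkv8-30 had the largest change of any named gene, 6.66 ± 0.37. Of 15 T cell genes, 4 rose, with Cd7 at 2.58 and the receptor chains Cd3e, Cd3d and Cd3g at 1.99, 1.89 and 1.81, and 4 rose over the list alone. Of 11 cytotoxic and natural killer cell genes, 4 rose, led by the chemokine Ccl5 at 2.57 and the granule proteases Gzmb at 1.82 and Gzma at 1.72, and 5 rose over the list alone. The 3 lists were called by camera with adjusted p of 4.17e-10, 1.03e-06 and 1.60e-06, and 0.0155 for each with an estimated correlation. Macrophage and dendritic cell genes did not pass (median log2 change 0.088, adjusted p = 0.234), nor did granulocyte and mast cell genes (median -0.057, adjusted p = 0.340).

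All 19 tested antigen processing and presentation genes had positive values, with a median of 0.88, and 7 rose, 10 over the list alone. They included the class II chains H2-Aa (1.93 ± 0.18) and H2-Ab1 (1.52 ± 0.16), the class II editor H2-DMa (2.02 ± 0.26) and the peptide transporter Tap1 (1.60 ± 0.26). All 35 tested interferon response genes had positive values too, with a median of 0.89, and 9 rose, 19 over the list alone. The immunity-related GTPases Igtp and Irgm2, which answer to interferon gamma, were higher by 2.87 ± 0.37 and 2.31 ± 0.38, and Usp18 and Oas1a, which answer to interferons in general, by 2.37 ± 0.32 and 2.09 ± 0.20. The camera adjusted p was 1.37e-23 for the presentation list and 5.14e-31 for the interferon list. On wild type replicate 2, whose actin ratio was like that of the Rag1 arrays, the medians of these lists above the Rag1 mean were 1.22 and 1.29.

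The antimicrobial list went the other way. Of 18 tested members, 15 had negative values and 3 fell, Reg3g, Reg3b and Pla2g2a, the last a secreted phospholipase of Paneth cells that fell by 1.71 ± 0.26 (adjusted p = 0.0173); 6 fell and 1 rose over the list alone. The list was called lower with an adjusted p of 1.58e-10, and 0.0165 with an estimated correlation. Reg3b had rank 2 among all probe sets on each Rag1 array, so normalization gave it the same value on those arrays and no spread there. Other genes lower on the wild type arrays were Tifa, an adaptor of innate immune signalling, which fell by 2.81 ± 0.23 (adjusted p = 0.000132), Duoxa2, the maturation factor of the hydrogen peroxide producing enzyme Duox2, by 1.65 ± 0.29 (adjusted p = 0.0407), and the epithelial kinase Ptk6 by 1.66 ± 0.25 (adjusted p = 0.0137). Soga1 (-1.64), Stom (-1.49), Ceacam20 (-1.43) and the monocarboxylate transporter Slc5a8 (-1.19) fell as well. Duoxa2 was the only called member among 38 oxidative and nitrosative stress genes, whose list did not pass (adjusted p = 0.919). Nos2, the inducible nitric oxide synthase, was too dim for the main test; its deposited intensity was at least 39.8 on the Rag1 arrays and 6.71 to 10.3 on the wild type arrays, and with no filter its log2 change was -1.28 with an adjusted p of 0.131.

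Several metabolic lists shifted with few or no single genes called. Fatty acid oxidation and ketogenesis genes were called higher (22 of 25 positive, median 0.20, adjusted p = 4.85e-05), and so were xenobiotic metabolism genes (29 of 37 positive, median 0.44, adjusted p = 2.83e-06, 0.117 with an estimated correlation), cell cycle genes (25 of 28 positive, median 0.28, adjusted p = 1.99e-05, 0.203 with an estimated correlation) and lipid absorption genes (24 of 31 positive, median 0.12, adjusted p = 0.00344, 0.267 with an estimated correlation). Cholesterol synthesis genes (16 of 20 negative, median -0.20, adjusted p = 0.0105, 0.411 with an estimated correlation) and crypt and stem cell genes (11 of 17 negative, median -0.12, adjusted p = 0.0114, 0.317 with an estimated correlation) were called lower. Of these lists, only fatty acid oxidation kept its call with an estimated correlation. No member of these 6 lists passed singly. Adjusted over the list alone, 5 xenobiotic genes, 1 fatty acid oxidation gene and 2 lipid absorption genes rose, 1 lipid absorption gene and 2 crypt genes fell, and no cell cycle or cholesterol gene passed. Circadian clock genes were called higher (adjusted p = 0.000864) with 1 called member, Dbp, a transcription factor of the clock's output, at 2.95 ± 0.45 (adjusted p = 0.0171), and 2 over the list alone. Pck1, the gluconeogenic enzyme, was the 1 member of the carbohydrate and peptide list that rose, by 2.09 ± 0.30, and that list did not pass (adjusted p = 0.307). Pigr, which carries IgA across the epithelium, differed by -0.13 ± 0.14 (adjusted p = 0.999) on its brighter probe set and by -0.69 ± 0.22 (adjusted p = 0.557) on the other. Lists with no call here were the cytokine list (adjusted p = 0.0557), goblet and enteroendocrine cells (0.0718), immediate early genes (0.0718), smooth muscle and stroma (0.0814), the unfolded protein response (0.139), bile acid transport (0.877), pancreas, fat and red blood cells (0.919) and genes next to Rag1 (0.234), where Cd59a was the 1 gene that rose, by 1.54 ± 0.23 (adjusted p = 0.0141).

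With an estimated correlation, 8 of the 13 list calls held: B cell, T cell, cytotoxic, antigen presentation, interferon, antimicrobial, fatty acid oxidation and clock genes, with adjusted p between 0.0155 and 0.0483. The count of 89 probe sets was less stable than the lists: it was 38, 39 and 41 without Rag1 replicates 1, 2 and 3, 37, 47 and 38 without wild type replicates 1, 2 and 3, and 354 without BP replicate 2 (227 higher and 127 lower). With the 3-prime to 5-prime ratio as a covariate 167 were higher and 127 lower. Fitting only the wild type and Rag1 arrays, which leaves out the larger BP spread, gave 213 higher and 125 lower. Array weights gave 529 higher and 521 lower, so the split into higher and lower depended on the spread used. Xist passed as well (5.34 ± 0.91, adjusted p = 0.0307), so the groups differed in sex-linked signal as well as in lymphocyte transcripts. Of the 36 named genes that passed, 15 passed with any single array left out, among them Igha, Jchain, Cd3e, Gzmb, H2-Aa, Igtp, Oas1a, Tifa, Reg3g and Reg3b. Of the lists, lipid absorption lost its call without Rag1 replicate 3 (adjusted p = 0.210), cholesterol without Rag1 replicate 3 (0.809) and without wild type replicate 1 (0.137), and crypt genes without Rag1 replicate 3 (0.0853) and without wild type replicate 2 (0.0758).

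**Figure D2:**
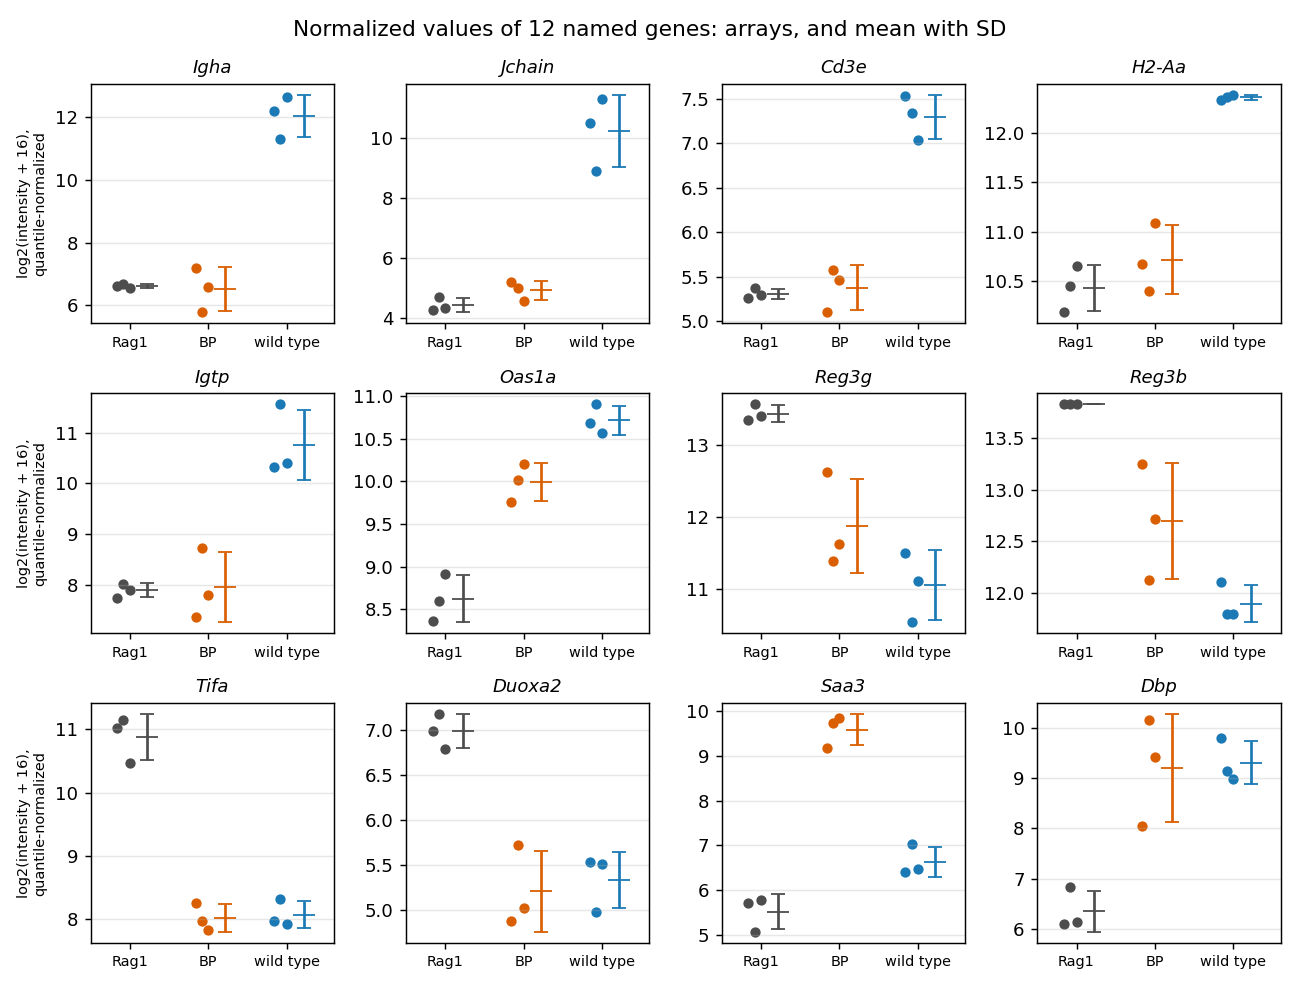
Points are the 3 arrays of each group, and the bar beside them is the mean with its standard deviation, in log2(intensity + 16) after quantile normalization; the vertical axes differ between genes and do not start at 0. Igha, Jchain, Cd3e, H2-Aa and Igtp are high on the wild type arrays only, whereas Tifa, Reg3g, Reg3b and Duoxa2 lie below the Rag1 arrays on every BP and wild type array.

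The comparison of BP with Rag1 tissue had the same source label on both sides and asked what the BP condition adds. The BP arrays had higher Saa3, an acute-phase protein, by 4.07 ± 0.29 on the log2 scale (SE, n = 3 per group; adjusted p = 0.000306), and higher Ccl8, a chemokine for monocytes, by 2.93 ± 0.36 (adjusted p = 0.0061). They had lower Tifa (-2.86 ± 0.23, adjusted p = 0.000542) and lower Reg3g and Reg3b, which fell by 1.55 ± 0.30 (adjusted p = 0.0220) and 1.13 ± 0.22 (adjusted p = 0.0224). Igha and Jchain did not pass, with differences of -0.11 ± 0.37 (adjusted p = 0.915) and 0.49 ± 0.48 (adjusted p = 0.637). Sex-linked signal differed as well. The brightest Xist probe set changed by 3.60 ± 0.91 (adjusted p = 0.0518, and 0.0495 with no filter). Eif2s3y, with no filter, changed by -1.87 (adjusted p = 0.0188), and no further probe set of either gene passed. A part played by sex in this comparison was not tested. In all, 298 probe sets were higher and 729 lower, for 243 and 612 genes. The fit shared 1 spread over all arrays, though the median standard deviation was 0.44 for BP, 0.21 for Rag1 and 0.23 for wild type. Fitting only the BP and Rag1 arrays gave 33 higher and 150 lower, and 31 of the 59 named genes that passed lost the call.

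Higher genes came from several functions. Dbp was up by 2.85 ± 0.45, the membrane protein Tm4sf4 by 2.68 ± 0.29, the mannose-binding lectin Mbl2 by 2.28 ± 0.35 and Wfdc17 by 2.03 ± 0.23. Metabolic genes included the aldo-keto reductases Akr1c19 (2.66) and Akr1c13 (2.06), the peroxisomal thiolase Acaa1b (2.27) and the retinol dehydrogenase family member Rdh16f2 (2.03); Trim7 was higher by 2.16. Besides Tifa, lower genes included the channel kinase Trpm7 (-2.40), Cdca4 (-2.34), the magnesium transporter Cnnm4 (-2.09), Pphln1 (-1.96), Trib1 (-1.85), Gga2 (-1.78), the tight junction protein Cgn (-1.78) and the glycosyltransferases B3gnt3 (-1.91) and St3gal4 (-1.89). The adjusted p of these lower genes after Tifa lay between 0.00719 and 0.0396. Trpm7, Trib1 and Cgn had 1 other tested probe set each and Cdca4 had 2, and none of these was called. The other probe set of Cnnm4 was called lower too. Averaged over all probe sets of a gene, 16 of 18 called genes kept their direction and 2 reversed. The high actin ratios of BP replicates 1 and 3 moved with this comparison, and without those arrays and with BP replicate 2 as the lone BP array the count was 2599 higher and 3379 lower.

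Of 4 lists called between BP and Rag1, none kept its call with an estimated correlation. Xenobiotic metabolism genes were called higher (29 of 37 positive, median 0.41, adjusted p = 0.000265, 0.611 with an estimated correlation): 5 rose, 9 over the list alone, among them Cyp3a11 (1.96 ± 0.44), the alcohol dehydrogenase Adh1 (1.62 ± 0.30) and the carboxylesterase Ces2a (1.27 ± 0.22), and Gstt3 fell by 1.40 ± 0.19. The list's median above the Rag1 mean was 0.20, 0.91 and 0.43 on BP replicates 1, 2 and 3. Fatty acid oxidation and ketogenesis genes were called higher (median 0.16, adjusted p = 0.0419, 0.611 with an estimated correlation), with 4 members up, such as Acaa1b and the pyruvate dehydrogenase kinase Pdk4 (1.28 ± 0.28), 7 over the list alone, and Cpt1a, which brings fatty acids into mitochondria, 2.46-fold lower (adjusted p = 0.0296). Averaged over all probe sets of a gene, Cpt1a was at 0.0099 and Acaa2, another of the 4 higher members, at -0.085, so both directions depended on the probe set. Macrophage and dendritic cell genes were called higher (median 0.13, adjusted p = 0.0419, 0.724 with an estimated correlation); the Fc receptor Fcgr3 (1.47 ± 0.25) was the 1 of 25 members that passed, and 2 passed over the list alone. Antigen processing and presentation genes were called lower (18 of 19 negative, median -0.37, adjusted p = 0.000265, 0.611 with an estimated correlation), where the immunoproteasome subunit Psmb8 (adjusted p = 0.00982), the class I chain H2-D1 (-0.90) and the class II chaperone Cd74 (-0.76) fell; 3 fell over the list alone. On BP replicates 1, 2 and 3 the median of this list below the Rag1 mean was -0.27, -0.53 and -0.34.

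The other 21 tested lists did not pass. Among interferon response genes 5 rose, including Oas1a (1.37 ± 0.20), Rsad2 (1.36 ± 0.29), Ifit1 (1.31 ± 0.31) and Oasl2 (1.28 ± 0.24), and Ido1 fell, but the list had a median of 0.076 and an adjusted p of 0.231. Antimicrobial genes had a median of -0.28 and an adjusted p of 0.142: Saa3 rose while Reg3g, Reg3b and Pla2g2a (-1.67 ± 0.26) fell. Duoxa2 fell by 1.78 ± 0.29, and Gpx2, Srxn1 and Gsr, which act against oxidants, by 0.51, 0.67 and 1.12, in a list whose adjusted p was 1.00. Single members fell in the cytotoxic list (the pore-forming Prf1, -1.71 ± 0.27; list adjusted p = 0.280), the cytokine list (Bcl3, -0.84; 0.197), the goblet and enteroendocrine list (the mucin Muc2, -0.53; 1.00), the lipid absorption list (Lpl, -1.05; 0.420), the crypt list (Axin2, -1.12; 0.402) and the immediate early list (Fos, -1.11; 0.231). The muscle genes Myh11 and Des fell by 1.51 and 0.69 in a list with an adjusted p of 0.375. In the bile acid list Abcc2 rose by 0.95 (list adjusted p = 0.231), and in the carbohydrate and peptide list Pck1 rose by 1.54 and Cdhr5 fell by 0.47 (list adjusted p = 0.757). Globin transcripts moved apart, with Hbb-b2 up by 2.59 ± 0.39, Alas2, the heme enzyme of red cells, up by 1.58 ± 0.28 and Hba-a2 lower at -2.48 ± 0.48 (list adjusted p = 1.00). The brighter Pigr probe set differed by -0.26 ± 0.14 (adjusted p = 0.346), whereas the other fell by 1.74 ± 0.22 (adjusted p = 0.00719), so the Pigr value depended on the probe set. Among genes next to Rag1, Slc1a2 fell by 1.24 (list adjusted p = 1.00). Other tested probe sets of Slc1a2, Srxn1, Axin2, Myh11, Pck1 and Rsad2 were not called. Nos2 read 11.7 to 20.0 on the BP arrays, and with no filter its log2 change from Rag1 was -1.03 with an adjusted p of 0.0773.

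The count of 1027 probe sets was 18, 23 and 212 without Rag1 replicates 1, 2 and 3, 598, 5303 and 223 without BP replicates 1, 2 and 3, and 466 and 453 without wild type replicates 1 and 3, and centring each array on its median gave 158 higher and 1054 lower. Under that centring the median over all probe sets moved to -0.12, which is the level against which those changes stand. As deposited, with no normalization, 130 were higher and 641 lower. Of the 59 named genes that passed, 4 passed with any single array left out: Saa3, Tifa, Tm4sf4 and Wfdc17. The xenobiotic list lost its call without BP replicate 2 (adjusted p = 0.291). Fatty acid oxidation genes lost theirs without BP replicate 2 (0.291), without Rag1 replicate 3 (0.119) and without wild type replicate 2 (0.0656). Macrophage genes did so without Rag1 replicate 1 (0.0814), without Rag1 replicate 2 (0.143), without BP replicate 2 (0.177), without BP replicate 3 (0.212) and without wild type replicate 2 (0.0656), and also with the 3-prime to 5-prime ratio as a covariate (0.646) and without BP replicates 1 and 3 (0.323). Their median above the Rag1 mean was 0.24, 0.078 and 0.37 on BP replicates 1, 2 and 3, in the order of the actin ratios of these arrays.

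The comparison of wild type with BP tissue asked how far the BP arrays remained from wild type. Antibody, T cell, cytotoxic, antigen presentation and interferon response genes were again higher on the wild type arrays. With an estimated correlation the presentation and cytotoxic lists kept their calls (both at an adjusted p of 0.0190), whereas the T cell (0.0529), B cell (0.107) and interferon (0.116) lists did not. Igha was higher by 5.54 ± 0.37 on the log2 scale (SE, n = 3 per group; adjusted p = 2.38e-05), H2-DMa by 2.75 ± 0.26 (adjusted p = 0.000371) and Igtp by 2.80 ± 0.37 (adjusted p = 0.00588). Saa3 fell by 2.95 ± 0.29 (adjusted p = 0.000493). In all, 155 probe sets were higher and 16 lower on the wild type arrays, for 114 and 12 genes.

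All 19 antigen processing and presentation genes had positive values with a median of 1.47, and 10 rose, 17 over the list alone (list adjusted p = 1.58e-25), among them Psmb8 (2.08 ± 0.18), Cd74 (1.98 ± 0.18) and H2-Eb1 (1.95 ± 0.27). Of 11 cytotoxic genes, 4 rose, Ccl5 (2.47 ± 0.26), Nkg7 (2.20 ± 0.28), Gzma (2.15 ± 0.24) and Gzmb (1.68 ± 0.22), and 7 over the list alone (list adjusted p = 3.09e-07). Of 15 T cell genes, Cd3g (2.55 ± 0.26), Cd7 (2.46 ± 0.40) and Cd3e (1.92 ± 0.24) rose, 4 over the list alone (list adjusted p = 0.000512). Igha, Jchain (5.31 ± 0.48) and Iglv1 (2.80 ± 0.43) rose among B cell and plasma cell genes, 7 over the list alone (list adjusted p = 4.80e-05), and Igkv8-30 and Igk were higher by 6.57 and 4.88. Among 35 interferon response genes, 31 had positive values, and Igtp, Irgm2 (2.44 ± 0.38), Irgm1 (2.27 ± 0.34), Ido1 (2.13 ± 0.26) and Ifi47 rose, 19 over the list alone (list adjusted p = 6.38e-13). Ubd, a ubiquitin-like modifier induced by interferon gamma, was higher by 3.13 ± 0.49.

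Cell cycle genes were called higher with no member past the threshold singly (23 of 28 positive, median 0.27, adjusted p = 0.00381, 0.481 with an estimated correlation) and 2 past it over the list alone. Antimicrobial genes were called lower (15 of 18 negative, median -0.50, adjusted p = 0.000512, 0.166 with an estimated correlation), with Saa3 as the 1 member that passed and Reg3g at -0.82 ± 0.30 (adjusted p = 0.222). Herpud1, of the unfolded protein response, rose by 0.98 ± 0.17 in a list that did not pass (adjusted p = 0.0562). Hbb-b2, Wfdc17 and the platelet chemokine Pf4 fell by 2.68 ± 0.39, 1.56 ± 0.23 and 1.56 ± 0.30. Macrophage genes did not pass (median -0.23, adjusted p = 0.0595), nor did clock genes (median 0.36, adjusted p = 0.0595).

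The count of 171 probe sets was 71, 70 and 77 without Rag1 replicates 1, 2 and 3, 110, 3046 (1950 higher and 1096 lower) and 81 without BP replicates 1, 2 and 3, and 58, 56 and 69 without wild type replicates 1, 2 and 3. Centring each array on its median gave 479 higher and 20 lower, against a median over all probe sets of 0.13. Fitting only the wild type and BP arrays gave 45 higher and 6 lower. Of the 27 named genes that passed, 16 passed with any single array left out, and the cell cycle list lost its call without BP replicate 2 (adjusted p = 0.0982). With the 3-prime to 5-prime ratio as a covariate 1987 were higher and 1501 lower, so the split into higher and lower was not stable. Settings tied to the actin ratio ended some list calls. The T cell list was lost with the 3-prime to 5-prime ratio as a covariate (0.0933), without BP replicates 1 and 3 (0.175), without wild type replicates 1 and 3 (0.0527) and without BP replicates 1 and 3 and wild type replicates 1 and 3 (0.507). The B cell list was lost without BP replicates 1 and 3 (0.0543) and without wild type replicates 1 and 3 (0.0527), and the antimicrobial list with the ratio as a covariate (0.0561) and without BP replicates 1 and 3 (0.0620). With the ratio as a covariate and without BP replicates 1 and 3, all 27 named genes kept their direction and call, whereas without wild type replicates 1 and 3 only 7 of the 25 still tested kept the call and 0 reversed.

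**Figure D3:**
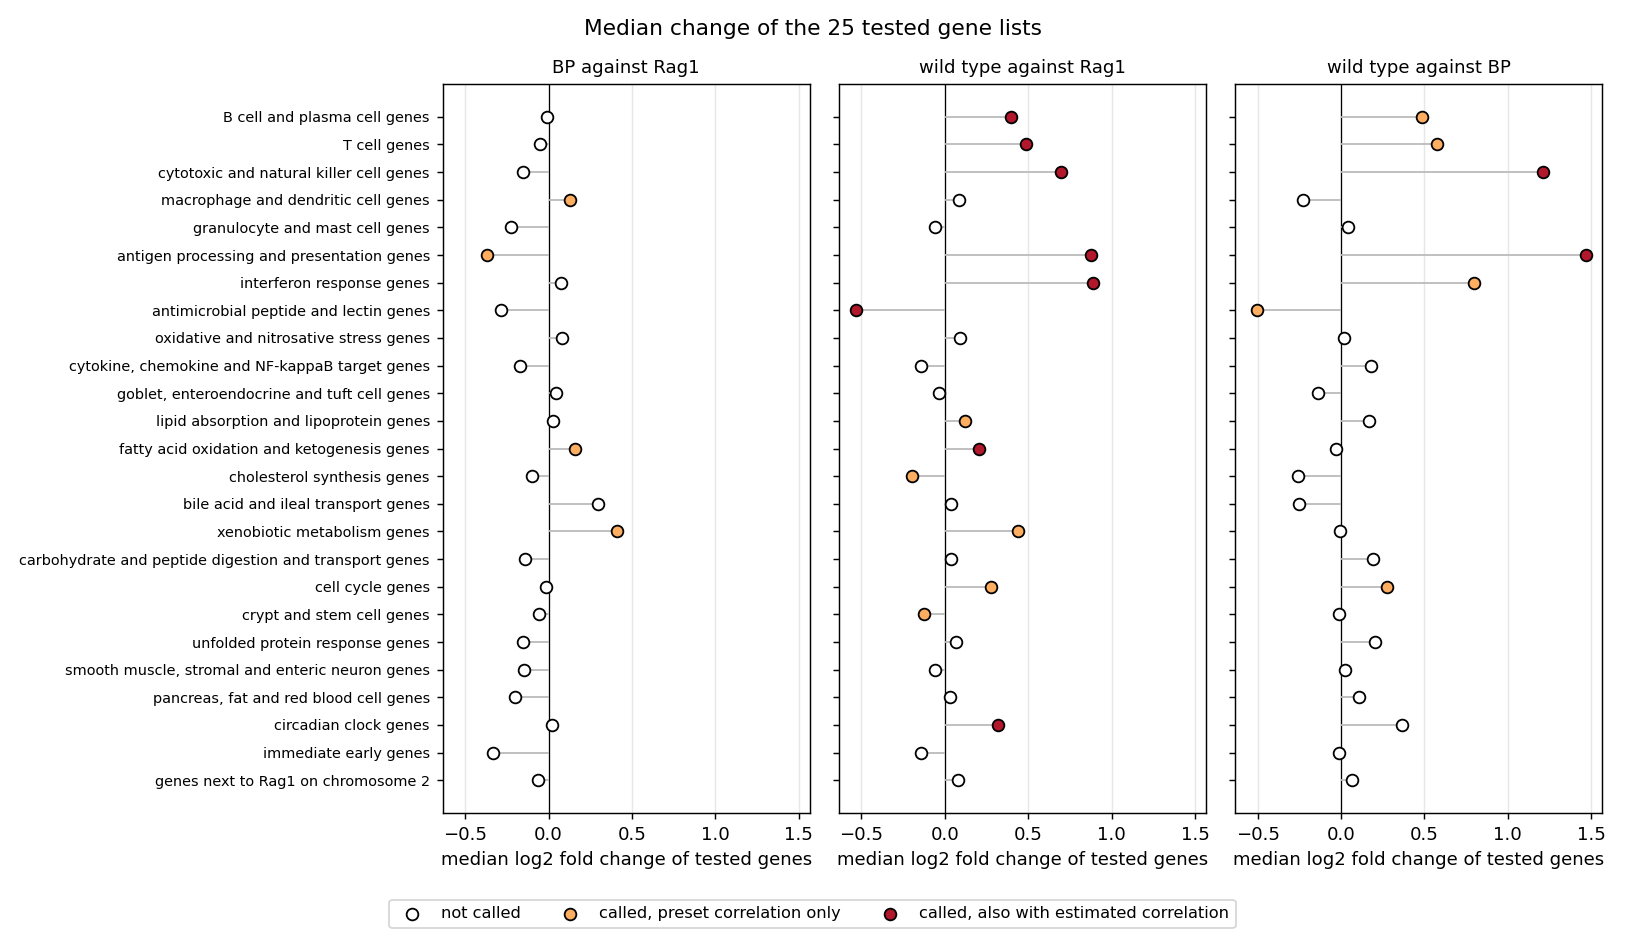
Each point is the median log2 fold change over the tested members of 1 of the 25 tested lists, with 1 panel per comparison; colour shows whether camera called the list. The presentation list lies at 0.88 above Rag1 and 1.47 above BP on the wild type arrays, and at -0.37 between BP and Rag1.

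Genes that separated wild type from Rag1 tissue were then followed on the BP arrays, each by its brightest tested probe set, which leaves 43 of the 47 higher and 10 of the 12 lower genes. All 10 genes that were lower in wild type also had negative BP minus Rag1 values, with a median of -1.31, and 9 of them passed there too: Reg3b, Reg3g, Stom, Ceacam20, Tifa, Pla2g2a, Ptk6, Soga1 and Duoxa2. On each of BP replicates 1, 2 and 3, all 10 genes lay below the lowest Rag1 array. Of the 43 genes higher in wild type, 28 had positive BP minus Rag1 values; 12 passed as higher on the BP arrays and 1, Cd74, as lower. The 12 included Dbp, Mbl2, Pck1, Oas1a, Oasl2 and Ifit1, and 26 of the 43 were higher in wild type than in BP. The median BP minus Rag1 value of those 43 genes was 0.14, against 1.89 for wild type minus Rag1.

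By probe set, 16 were lower and 15 higher in both comparisons, where independent lists would share 0.51 and 0.77; 5 were higher in wild type and lower in BP (1.89 by independence) and 0 the reverse (0.21). Both comparisons use the Rag1 arrays, so their values are tied even with no effect. By probe set, 19 of the 19 lower in wild type and 43 of the 70 higher had the same sign in BP, where simulations with the wild type changes and no BP change gave 62.0% and 54.3%. In 50 simulations with the wild type changes and no BP change, at most 1 of the probe sets lower in wild type was called lower in BP and none of the higher ones was called higher, and with no change in either group no probe set was called in both. Across 13570 genes, which are not independent replicates, the covariance of the differences was 0.0841, against 0.0458 ± 0.0010 (SD, 100 simulations) for unchanged groups, and the correlation was 0.49 against 0.50. Without wild type replicates 1 and 3 the covariance was 0.0467, against 0.0534 ± 0.0017 simulated for that setting. With pseudocount 64 it was 0.0481 against 0.0220 ± 0.00056. All of these simulations gave every array the same spread per gene, whereas the median standard deviation was 0.21 for Rag1 and 0.44 for BP. They therefore cannot settle whether the excess depended on wild type replicates 1 and 3. Splitting 3 Rag1 arrays would leave fewer than 2 in a part and was not done. The simulations include the sharing of these arrays only at the assumed spread. The part due to sharing depends on the spread of the Rag1 arrays, whose median was the smallest, so the simulated values probably overstate it. No simulation used a separate spread per group, so how much of the covariance comes from sharing stays unsettled.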

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

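The signals below lie in control probe sets or in probe sets that were too dim for the tests. The tests on the genes lower in both wild type and BP, and those with the actin ratio as a covariate, were chosen only after the values were seen. The other tests were chosen after the patterns were noticed, but before the values they measure were seen.

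On BP replicate 2 the Dap and Thr 3' controls, bacterial transcripts that can be added to RNA before labelling, read 1019 and 485, against at most 19.1 and 33.1 on any other array, and the 18S ribosomal RNA 3' control read 1862 against at most 273. The beta-actin 3' to 5' ratio was 14.2 on BP replicate 1 and 20.2 on BP replicate 3, against at most 4.17 on any other array. Eif2s3y read at least 44.9 on the Rag1 arrays and at most 17.0 elsewhere. Nos2 read at least 39.8 on the Rag1 arrays and at most 20.0 elsewhere.

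More probe sets were lower than higher on the BP arrays, 729 against 298. Shortened RNA is a candidate explanation for a part of this: over the 729 lower probe sets, wild type replicates 1 and 3, which have raised actin ratios, lay below wild type replicate 2 by a median of -0.36, where 95% of 1000 random lists matched on intensity lay between -0.0046 and 0.046, and the 298 higher probe sets went the other way, at 0.30. With the actin ratio as a covariate an excess remained, 2376 lower against 1815 higher, so the BP condition stays open. Within BP, replicates 1 and 3 differed from replicate 2 by -0.15 over the lower and -0.058 over the higher probe sets. These sets were chosen for their difference from Rag1, which also favours a small spread within BP, so these values decide nothing. A different preparation of BP replicate 2 was not needed for an excess, since without it 3066 were lower and 2237 higher, but the share of 57.8% lay between the limits of 55% and 60% set for the test, so a part played by it stays open. Of the 10 splits of the 6 arrays, 1 gave as many calls, the real one with 1027 against at most 0 for the others, and 10 splits are too few for a share under 0.05.

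Reg3g, Reg3b, Tifa, Duoxa2 and 6 other genes had lower values on the wild type arrays and on the BP arrays than on the Rag1 arrays. The values argue against shortened RNA, as read by the actin ratio, as the whole cause: with the ratio as a covariate all 10 still passed in wild type against Rag1, at a median of -1.64 (median SE 0.22) against -1.66 (0.24) without it, and 8 rather than 9 passed in BP against Rag1, where Ptk6 lost its call as its value went from -1.13 ± 0.25 to -0.82 ± 0.33, smaller and with a larger error. Wild type replicates 1 and 3 lay above replicate 2 by 0.19, inside the range of random lists (-0.15 to 0.22), which decides nothing. Sex stays open, since the brightest Xist probe set and the brighter Eif2s3y probe set separate the wild type and Rag1 arrays completely. BP replicate 1, with the pattern nearest to the Rag1 arrays, lay at a median of -1.04 for these 10 genes. That was below the -0.36 that bounds 95% of random lists. But the 10 genes were chosen as higher on the same Rag1 arrays, and the random lists were not. This comparison, which also rests on 1 array, cannot exclude sex. Lymphocytes in the tissue are argued against for the BP side, where Igha and Cd3e differed from Rag1 by -0.11 ± 0.37 and 0.07 ± 0.24 (5.44 ± 0.37 and 1.99 ± 0.24 in wild type), while a response to IgA, which the series title names, stays open and was not tested.

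Dbp was higher on the wild type arrays and on the BP arrays than on the Rag1 arrays. A different hour of tissue collection may contribute: clock genes that peak with Dbp exceeded those that peak opposite by 0.90 in wild type minus Rag1 (9 against 5 genes, exact one-sided permutation p = 0.00749 over genes, which are not independent). All 9 genes of the first kind were positive. Of the second kind, Nfil3, Npas2, Cry1 and Arntl were negative (-0.57, -0.44, -0.22 and -0.18), and Clock was unchanged at -0.00044. For BP minus Rag1 the difference was 0.21 (exact permutation p = 0.128), and the labels give no hour. A change of the clock by the genotype predicts the same signs and was not tested.

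For wild type against Rag1, 1 of 10 splits of the 6 arrays gave as many calls, the real one with 89 and the highest other with 0. For wild type against BP, 1 of 10 did, with 171 and a highest other of 1. With 10 splits the share cannot fall under 0.05.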

How the results depend on the processing

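The values as deposited, the actin ratio as a covariate, the filter by group and the settings that leave out 2 or 4 arrays were chosen after seeing the data. Quantile normalization, listed as an alternative, was not run as one because it became the main setting. For a lone array left in a group, its spread was assumed to be that of the other groups. The cause was not tested for any change below, except that a stricter threshold leaves fewer calls by construction.

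Changed probe sets numbered 1027 for BP against Rag1, 89 for wild type against Rag1 and 171 for wild type against BP. Leaving out 1 array gave 18 to 5303, 37 to 354 and 56 to 3046. In the same order, fitting only the groups compared gave 183, 338 and 51, array weights 4023, 1050 and 856, an adjusted p under 0.01 gave 78, 42 and 52, and the actin 3' to 5' ratio as a covariate 4191, 294 and 3488. Without BP replicates 1 and 3 they were 5978, 338 and 5700, without BP replicates 2 and 3 they were 3255, 350 and 1387, without wild type replicates 1 and 3 they were 185, 19 and 30, and without all 4 of BP and wild type replicates 1 and 3 they were 6410, 174 and 3888. Without the intensity trend BP against Rag1 gave 518 and wild type against BP 89. Wild type against BP gave 499 with each array centred on its median and 108 as deposited. Under all these settings BP against Rag1 had more lower than higher probe sets, with a lower share between 55.6% and 87.0%.

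Lists called numbered 4, 13 and 7, and leaving out 1 array gave 1 to 4, 10 to 17 and 7 to 9. With an estimated correlation they numbered 0, 8 and 2. With fry, BP against Rag1 had 0 and wild type against Rag1 8. For BP against Rag1, the pseudocount 64, no filter, only the groups compared, and leaving out wild type replicates 1 and 3 gave 2 each, and array weights and leaving out BP replicates 2 and 3 gave 1 each. For wild type against BP, only the groups compared gave 12 and array weights 11. In wild type against Rag1, the B cell, T cell, cytotoxic, presentation, interferon, antimicrobial, fatty acid oxidation and clock lists were called under all 29 other settings.

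With the replicate number as a block, wild type against BP had 11 lists and the changed probe sets numbered 799, 74 and 142. The numbers did not pair the samples, since correlations of arrays with the same number lay between -0.19 and 0.23.

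The covariance of the differences from Rag1 was 0.0841 and, leaving out 1 array, 0.0741 to 0.104. It was 0.122 with the pseudocount 1, 0.0481 with 64, 0.0766 with no filter, 0.0899 with the lowest 60% left out, 0.102 with array weights and 0.189 with the actin covariate. Without BP replicates 1 and 3 it was 0.0705, without BP replicates 2 and 3 it was 0.0830, without wild type replicates 1 and 3 it was 0.0467, and without all 4 it was 0.0602.

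Of 1545 values for the 59 named genes that passed in BP against Rag1, 1166 kept direction and call, 377 lost the call and 2 reversed: averaged over all their probe sets, Acaa2 was -0.085 and Cpt1a 0.0099. For wild type against Rag1, 769 of 938 values were kept and 169 lost the call, and for wild type against BP 621 of 704 were kept and 83 lost it, with 0 reversed in either. Dim signal limits what can be read: probe sets under a mean intensity of about 23.5 were not tested.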

Other observations

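Genes close to Rag1 on chromosome 2 were listed because a knockout can carry flanking DNA of another strain. Cd59a was higher on the wild type arrays than on the Rag1 arrays (log2 change 1.54 ± 0.23, adjusted p = 0.0141) and than on the BP arrays (1.21 ± 0.23, adjusted p = 0.0422), and 15 of the 25 tested genes of the list were positive in each of these comparisons. The list was not called in either (adjusted p = 0.234 and 0.384). Of the 9 fits that left out 1 array, Cd59a lost its call in 6 for wild type against Rag1. It lost its call in 8 of them for wild type against BP. The other tested Cd59a probe set was not called in wild type against Rag1. A planned test of whether changed genes cluster around Rag1 was not run, because 3 other patterns were weighed instead. No test was chosen for this part after its values were seen.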
